A study of Mus musculus with 360 samples.

How the data were processed

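C1498 cells, a mouse acute myeloid leukemia line, were heated at 45 °C for 10 min, or handled alike at 37 °C as the control, and then followed under the microscope. Single cells were picked by an automated imaging and picking instrument at -1, 1, 5, 10 or 15 h from the end of heating. Each sample of the series was 1 cell, and its treatment label gave the temperature and the time, which made 10 groups and 360 cells. Per the labels' protocols, RNA was fragmented by heat after lysis and reverse transcribed with a primer that carried a molecular barcode and a stretch of T. The products were extended by template switching and amplified by PCR.

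The deposited table held estimated counts of molecules (UMIs) per gene and cell, not scaled to any total. Of the 1732996 values above 0, 5.30% were not whole numbers (no tolerance was allowed), which is how molecules shared between genes appear when they are split. The values that were not whole held 25.9% of all UMIs, and where the fractions came from was not tested. STAR and the mouse build mm10 are named per the submitters' processing notes, without a version. The program that counted molecules, its gene annotation and any filter on cells are not given in the sources used here. The plan written before the data were examined assumed whole counts, and for a table without them it foresaw means with no interval. That fallback was not followed: because the values are estimated counts, sums were rounded to whole numbers and intervals were kept. This choice was made after the values had been seen. Spike-in RNA was added per the labels, but neither spike-in genes nor mitochondrially encoded genes were analysed here, so RNA content per cell is not reported.

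The UMIs of all cells of a group were summed per gene and divided by the group's total, giving CPM (the share of all UMIs, scaled to 1e6). Because no label names a culture, each group counted as 1 sample: no p-value, standard error or count of changed genes was computed from cells. The log2 ratio of 45 °C over 37 °C was taken after adding 0.5 UMI to each sum. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval, and shares of cells have the exact Clopper-Pearson interval. Both cover counting error only, not differences between cells or cultures. A group at 0 was given a floor of 3 counts over the group, which was between 0.441 CPM (45 °C 5 h) and 17.3 CPM (37 °C 10 h).

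Each of the 4 times after heating was compared with the 37 °C group of the same time. The pair before heating, and each later 37 °C group against the one before heating, served as background. A gene was measured where both groups together had at least 20 UMIs and 1 of them at least 10 CPM. Genes were named by a fixed rule. A candidate had at least 50 CPM in the higher group, a UMI in at least 50% of that group's cells, and a level in the 45 °C group outside the range of all 6 unheated groups. It also kept its direction with any single cell left out. Candidates were ranked by the interval bound nearest 0, up to 10 per direction. Predicted genes were left unnamed, and ribosomal protein genes too unless a list held them. The 25 gene lists, the markers of other cell types and this rule were set before the data were examined. For each list, the median log2 ratio of its measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart under percentile 2.5 or over 97.5, as a description of these libraries. The interval of a list median came from 1000 draws of the counts. After the values had been seen, each median was also set beside its range in the 5 comparisons of unheated groups. All 5 had the 37 °C group before heating as denominator, so the range carries any deviation of that group. For some lists it lay wholly under 0, such as ribosomal proteins (-0.168 to -0.027). Lying inside or outside it is thus a description, not a test against what is seen without heat. Examples from a list are the largest and smallest ratio and the members with the most UMIs.

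The lists were heat shock chaperones, chaperonin and prefoldin, ER unfolded protein response, ATF4 integrated stress response, immediate early genes, p53 targets, apoptosis regulators, NF-kB and cytokines, interferon response, oxidative and metal stress, S phase, G2 and M phase, ribosomal proteins, ribosome biogenesis, mitochondrially encoded genes, nuclear respiratory chain, glycolysis and hypoxia, cholesterol synthesis, proteasome, autophagy and lysosome, splicing kinases and SR proteins, temperature-sensitive RNA-binding proteins, heat shock factors, nuclear long noncoding RNAs, and actin cytoskeleton with SRF targets.

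For shares of cells and the Fano factor (variance over mean), every cell was thinned to 5000 UMIs. This left out 1 cell of 45 °C 5 h and 5 cells of 45 °C 10 h. Fano factors were computed for genes with a thinned mean of at least 0.5 UMI. Cells were never sorted by their own expression, and no cell filter was applied to the main values. No doublet caller was run, since cells were picked singly under imaging.

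Group sums ranged from 173274 UMIs (37 °C 10 h) to 6809101 UMIs (45 °C 5 h). On simulated counts for 45 °C 5 h against 37 °C 5 h with counting noise alone, the interval held the true log2 ratio for 96% to 98% of the 50 genes simulated at each of 1, -1, 2 and -2, and for 96.8% of the 7547 unchanged genes, among 7747 measured. With cells also varying beyond counting noise, it held the true value for only 56% to 66% of the genes at those ratios and for 83.2% of 7583 unchanged genes, among 7783 measured. That variation was a gamma factor of shape 2 for every gene in every cell, set by hand and not fitted to these data. At 45 °C 5 h the median gene varied less than this (Fano factor 1.13), while some, such as Rn4.5s (120.9), varied more. The intervals are thus too narrow for differences between cells, by an amount not measured in these data.

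Alternatives were the mean of per-cell CPM, only cells with at least 5000 UMIs, all 6 unheated groups or the 45 °C group before heating as control, library sizes from TMM factors, 5 CPM added in place of 0.5 UMI, every gene with a UMI, and each cell left out in turn. After the values had been seen, Rn45s was left out of the library size, and cells with over 30% of UMIs in Rn45s were left out. For the spread over genes, genes with at least 200 UMIs, or 6 cells drawn per group (median of 100 draws), were used. Shares of cells were repeated without thinning, at 1000 UMIs, and with at least 2 UMIs. Library sizes from spike-ins or without mitochondrial genes were not run.

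Of 24781 gene symbols, 24241 matched GENCODE release M21 and 24127 matched RefSeq, both on build GRCm38 (mm10), and 216 matched neither. Coordinates are from GENCODE, or from RefSeq for Rn4.5s. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors only.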

Results

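Mouse C1498 leukemia cells were heated at 45 °C for 10 min or kept at 37 °C, and single cells were picked by an imaging instrument before and after heating. RNA was counted in 360 cells, of which 51 were unheated. The heated groups held 13 cells at 1 h, 52 at 10 h and 21 at 15 h, and the largest, at 5 h, held 61.9% of all cells, and the 37 °C groups of the same times held 11, 6, 6 and 11 cells. Before heating, 11 cells of the 37 °C arm and 6 of the 45 °C arm had been picked. The median cell had between 18741 UMIs (45 °C 10 h) and 40544 UMIs (37 °C before heating). Every group was read as 1 sample, so the values below describe these cells, and their 95% intervals cover counting error only.

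The unheated cells carried RNAs of general leukocyte genes and of some T cell genes. Ptprc, which encodes the leukocyte surface phosphatase CD45, stood at 501.5 CPM in the unheated cells, and Coro1a, an actin regulator of blood cells, at 1144 CPM. Cd3e and Cd3g, components of the T cell receptor complex, stood at 199.2 and 230.1 CPM, while Cd3d stood at 4.71 CPM, Cd2 at 2.09 CPM and Nkg7 at 1.05 CPM, and Cd4, Cd8a, Klrb1c, Gzma, Gzmb, Prf1 and Il2rb had no UMI in unheated cells. The myeloid genes Lyz2, Elane, Spi1, Csf1r, Kit and S100a8 had no UMI in any of the 360 cells, and Mpo had 14 UMIs. Fcgr3, an Fc receptor gene, reached 48.99 CPM.

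Before heating, the arms already differed in cell cycle RNAs. The S phase list stood higher in the 45 °C arm (median log2 ratio 0.47) and the G2 and M phase list lower (-0.34), while the heat shock chaperone list stood at -0.06. Malat1, a nuclear noncoding RNA, was at 352 CPM in the 45 °C arm and 637 CPM in the 37 °C arm. The middle 90% of genes spanned 1.80 log2 units in this pair, against 1.70 at 1 h, 2.73 at 5 h, 2.68 at 10 h and 1.73 at 15 h. With 6 cells drawn per group these widths were 1.785, 1.877, 2.278, 2.43 and 1.985. Over genes with at least 200 UMIs they were 0.748, 0.828, 1.893, 1.543 and 0.997. By both alternatives, the widths at 1 h and 15 h lay above that of the pair before heating. The 200 UMIs counted both groups of a pair together, and these sums were larger after heating than before it. Genes of lower CPM thus passed at the later times, so these widths do not cover like genes. In the control arm alone, 10, 7, 5 and 9 lists stood apart from random lists at 1, 5, 10 and 15 h when set against the cells before heating. Heated groups against the 37 °C group of the same time had 7, 8, 9 and 8 such lists, and the pair before heating had 3. Standing apart alone therefore does not mark an effect of heating. For that reason several list medians are set below beside their range over comparisons of unheated groups, which all shared the 37 °C cells before heating as denominator. The median of all measured genes stood at -0.14, -0.23, 0.0030 and -0.02 at 1, 5, 10 and 15 h, so list medians at 1 and 5 h lie on a lowered base.

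At 1 h after heating, some short RNAs made by RNA polymerase III stood far above control. Rn4.5s, a rodent small nuclear RNA, was at 12951 CPM against 155.4 CPM (log2 6.37, 6.01 to 6.75). Rpph1, the RNA of ribonuclease P, was at 584 CPM against 2.53 CPM, which came from 1 control UMI (7.27, 5.36 to 13.2), and it stood at 8.69 without 37 °C 1 h cell 1. Rmrp, the RNA of the related ribonuclease MRP, was at 358.5 CPM against 0, at least 47.3-fold. Vaultrc5, a vault RNA, had 11 UMIs against 1, whereas Bc1, a neuronal RNA, had 1 against 2 and Rnu6, the U6 RNA, had 0 in both groups. In summed CPM of Rn4.5s, Rpph1 and Rmrp, which were summed after their difference had been seen, 13 of 13 heated cells (100%, 75.3% to 100%) exceeded the highest of the 51 unheated cells, which was at 2759 CPM.

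The chaperone response was small at this time. The heat shock chaperone list had a median log2 ratio of 0.15 (0.03 to 0.25), with 16 of 22 measured genes higher and 0 at least 2-fold higher. This lay within the range of unheated comparisons (-0.18 to 0.18), but relative to all genes it stood at 0.29, above that range (-0.21 to 0.18), and against all unheated groups the median was -0.0065. Hsph1, a cofactor of HSP70, was at 266 CPM against 164.3 CPM (0.69, 0.25 to 1.16), and the HSP90 genes Hsp90aa1 and Hsp90ab1 were at 1582 against 1265 CPM and 5405 against 4557 CPM. Bag3, which encodes an HSP70 partner, was at 22.98 against 30.3 CPM.

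Among other genes at 1 h, Samhd1, a dNTP hydrolase gene, was higher (log2 1.16, 0.51 to 1.88). Mpv17l and Trappc9 were also higher, at 2.57 and 2.24, and both leaned on 45 °C 1 h cell 13, without which they stood at 1.83 and 1.03. Trappc9 stood at 3.95 without 37 °C 1 h cell 1. Rsrc2, an SR-related splicing gene, was lower (50.6 against 202.2 CPM; -1.98, -2.75 to -1.30), as was Mat2a, which makes S-adenosylmethionine (114.9 against 306 CPM; -1.40, -1.92 to -0.93). Against all unheated groups, Rn4.5s stood at 5.28 and Trappc9 at 1.99. Rpph1, Rmrp, Mpv17l and Samhd1, whose control at 1 h was the lowest of these, stood at 4.79, 6.34, 1.505 and 0.54, and Rsrc2, Mat2a, Acot7, Sap30l and Rtn4rl1, whose control was the highest, at -1.43, -1.10, -1.10, -1.68 and -1.12. Acot7, Sap30l and Rtn4rl1 were lower at -1.59, -2.11 and -1.72, which became -0.83 without 37 °C 1 h cell 7, -2.84 without 45 °C 1 h cell 1 and -2.54 without 45 °C 1 h cell 3. The nuclear long noncoding RNA list stood lower (-0.66; 10 of 11 genes), with Malat1 at 299.9 against 592 CPM and Snhg8 at 59.8 against 161.7 CPM, although the Malat1 difference was there before heating. The cholesterol synthesis list stood higher (0.23; 12 of 15 genes). S phase genes stood higher (0.44; 27 of 31) and G2 and M phase genes lower (-0.33; 27 of 34), much as before heating and inside their unheated ranges (-0.19 to 0.47 and -0.41 to 0.16), although S phase relative to all genes, at 0.58, lay above its range. Both medians had the other sign against the 45 °C arm before heating (-0.09 and 0.20). The ATF4 list stood at -0.29, inside its unheated range (-0.65 to 0.28), but at 0.24 against all unheated groups and 0.06 against the 45 °C arm before heating.

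**Figure D1:**
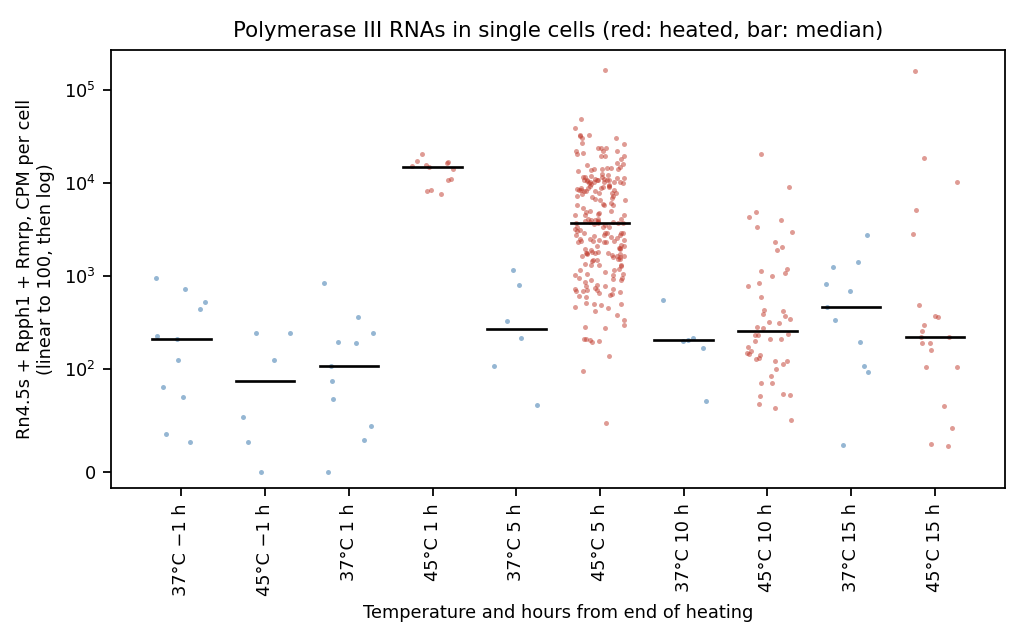
Summed CPM of Rn4.5s, Rpph1 and Rmrp in each cell, by temperature and time.

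At 5 h after heating, chaperone RNAs stood well above control. Bag3 was at 301 against 28.7 CPM (log2 3.29, 2.35 to 4.71), Dnajb1, an HSP40 gene, at 367 against 69.7 CPM (2.35, 1.71 to 3.18) and Hsph1 at 1838 against 365 CPM (2.32, 2.03 to 2.65). Hsp90aa1 was at 5202 against 1620.4 CPM (1.68, 1.54 to 1.83) and Hsp90ab1 at 9675 against 5243 CPM. The mitochondrial chaperonin genes Hspd1 and Hspe1 were at 3263 against 1707 CPM and 2621 against 1147 CPM. Hspa1a, the inducible HSP70 gene, was at 93.9 CPM against 0, or 7.63-fold over the floor. Only 8.52% of heated cells had a UMI of it without thinning, so 6 control cells could miss it. The floor is thus no lower bound on its fold. In unheated cells it was at 0 except in cell 4 of the 45 °C arm before heating (23.66 CPM), which rounded to no whole UMI. The constitutive Hspa8 was at 3296 against 3524.5 CPM and Hspa4 at 331 against 435 CPM. The list median was 0.88 (0.68 to 0.99), with 23 of 26 genes higher, 11 at least 2-fold higher (10 with a floor for genes at 0), and 21 above all 6 unheated groups. With the floor the median was 0.81.

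The share of cells in which a chaperone RNA was seen depended on depth. With every cell thinned to 5000 UMIs, Hsph1 was seen in 95.95% (92.4% to 98.1%) of the heated cells at 5 h, Dnajb1 in 68.02% (61.5% to 74.1%) and Bag3 in 63.96% (57.3% to 70.3%). In the 6 control cells the shares were 83.3% (35.9% to 99.6%), 33.3% (4.33% to 77.7%) and 16.7% (0.421% to 64.1%), so the intervals overlapped for each gene. Without thinning these shares were 99.55%, 94.17% and 90.58%, against 100%, 100% and 50% of control cells. At 1000 UMIs they were 72.65%, 26.91% and 24.22%, against 33.3%, 0% and 0%. Hspa1a was seen in 14 cells (6.31%, 3.49% to 10.35%) and its near-identical copy Hspa1b in 2.25% (0.735% to 5.18%), and how reads were split between these copies was not tested. The highest Hspa1a level, 7406 CPM, was in the shallowest cell (3443 UMIs), which thinning left out. Genes of other cell types without a UMI in unheated cells were present at low levels in the heated cells at 5 h, with Cd79a at 5.58 CPM, Mpo at 2.06 CPM and Prtn3 at 0.881 CPM. Over all cells these had 42, 14 and 6 UMIs. The heated sum at 5 h, 6809101 UMIs, was larger than that of all 6 unheated groups together, of which the largest had 453932. For Mpo and Prtn3, absence from the unheated cells therefore does not show a gain with heating. Per cell, Hsph1 had a median of 1588 CPM and a range from the 10th to the 90th percentile of 357 to 3593 CPM, and Hsp90aa1 had a median of 5284 CPM (2418 to 8413 CPM). Over all genes with enough UMIs the median Fano factor was 1.13, and those of Hspa1a, Hsph1 and Hsp90aa1 were 15.9, 6.75 and 5.96.

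**Figure D2:**
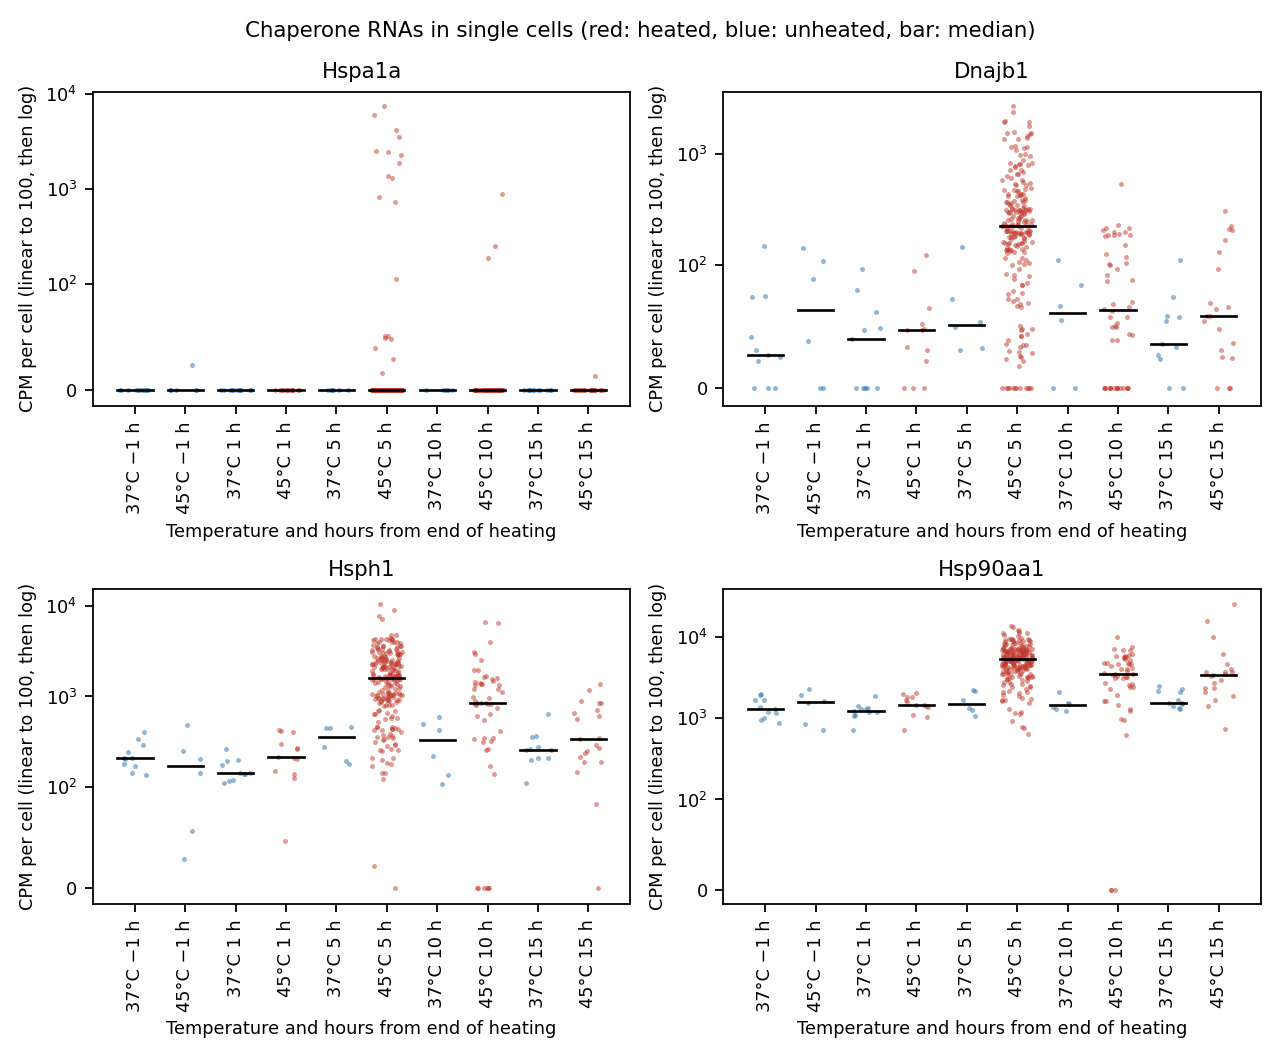
CPM of Hspa1a, Dnajb1, Hsph1 and Hsp90aa1 in each cell, by temperature and time, with the median of each group.

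Hist1h1b, Nasp, Rrm2 and Hist1h2ap were among the 10 genes named as lower at 5 h, with Slfn2, Ms4a4b, St8sia4, Snrnp35, Elf1 and Nlk. Hist1h1b, a linker histone gene, was at 9.11 against 98.5 CPM (log2 -3.45, -4.14 to -2.69) and Hist1h2ap, a core histone gene, at 225 against 697 CPM. Nasp, a histone chaperone gene, was at 135.3 against 463.5 CPM (-1.78), and Rrm2, a ribonucleotide reductase gene, stood at -1.81 (-2.13 to -1.46). Against all unheated groups, Hist1h1b, Nasp and Rrm2 stood at -2.67, -1.38 and -1.415, and for Hist1h1b and Nasp the control at 5 h was the highest unheated group. Slfn2, which guards T cell quiescence, was at 13.5 against 69.7 CPM. The S phase list stood at -0.36 (22 of 31 genes lower), outside its unheated range, but at -0.13 relative to all genes, inside it (-0.22 to 0.46). Rn4.5s remained high (5994 against 468 CPM; 3.67, 3.42 to 3.96), and Smad7, an inhibitor of TGF-beta signaling, was higher (215.5 against 36.9 CPM; 2.47), as was Uspl1, a SUMO protease gene (512 against 131.3 CPM). Kif3a, Rpph1 and Rmrp stood at 3.26, 2.99 and 3.71, which became 3.98 and 4.92 for Kif3a and Rmrp without 37 °C 5 h cell 4 and 3.71 for Rpph1 without cell 1, while against all unheated groups they stood at 2.33, 3.52 and 4.17. Rmrp had 1 control UMI at 5 h, which was lost without cell 4. Its 4.92 thus rests on the 0.5 UMI added and is no measured fold.

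Immediate early and ribosomal protein genes also stood higher at 5 h. The immediate early list stood at a median above control (0.91; 11 of 13 genes; 0.79 with the floor), with Ier2 at 150.5 against 57.4 CPM. Egr1 was at 15.6 CPM against 0, or 1.27-fold over the floor, and 15.7% of heated cells had a UMI of it without thinning. Myc, in contrast, was lower at -2.25, or -1.12 without 37 °C 5 h cell 2. Ribosomal protein genes stood slightly higher (0.26; 70 of 76 genes), with Rpsa at 6128 against 4778 CPM. ER unfolded protein response genes stood lower (-0.36; 16 of 19), outside their unheated range, but at -0.130 relative to all genes, just inside it (-0.135 to 0.22), with the ER chaperone gene Hspa5 at 335 against 799.9 CPM and the lectin chaperone gene Calr at 541 against 808 CPM. The nuclear long noncoding RNA list stood at 0.32 (9 of 12 higher), inside its unheated range (-0.06 to 0.52), but at 0.55 relative to all genes, just above it, with Gas5 at 566.5 against 330.2 CPM. Ribosome biogenesis genes stood at -0.33 (23 of 29 lower), outside their unheated range, but at -0.10 relative to all genes, inside it, and at 0.05 against the 45 °C arm before heating. The ATF4 list stood at 0.28 (15 of 19 genes higher), but at -0.24 against the 45 °C arm before heating. The glycolysis and hypoxia list stood at 0.20, but at -0.10 against all unheated groups. The NF-kB list stood at -0.43 with 7 of 7 genes lower, outside its unheated range, but at -0.20 relative to all genes, inside it.

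**Figure D3:**
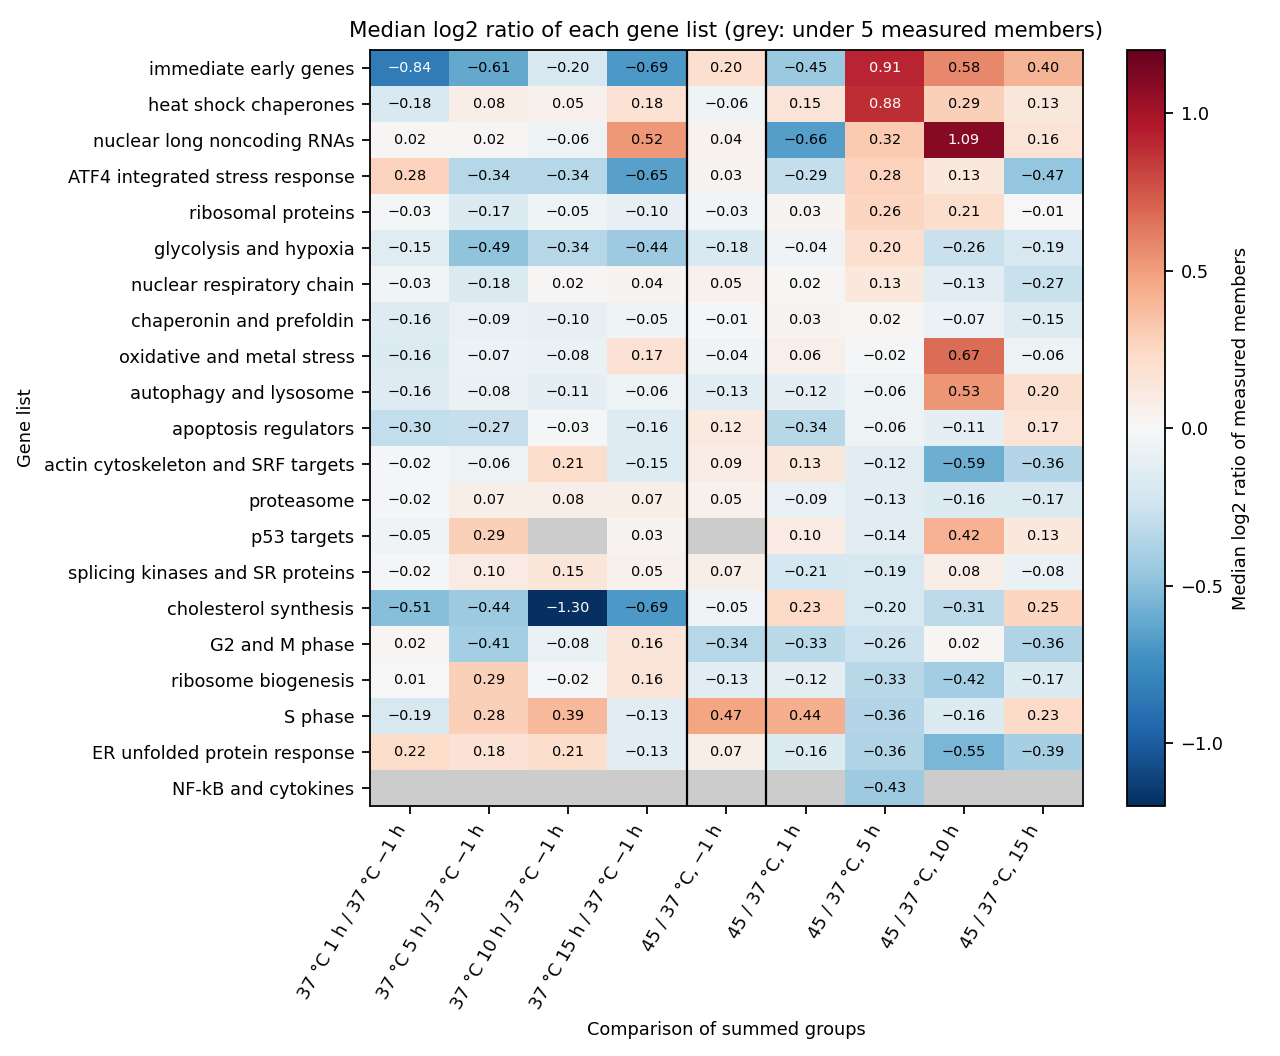
Median log2 ratio of each gene list in each comparison of groups, grey where under 5 genes were measured.

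At 10 h after heating, oxidative stress genes and the autophagy receptor gene Sqstm1 stood higher. Sqstm1, which encodes p62, was at 428 against 17.3 CPM, the latter from 3 UMIs (log2 4.41, 3.07 to 6.91), and Osgin1, an oxidative stress gene, was at 203.1 against 34.6 CPM (2.44, 1.41 to 4.02). The ferritin genes Ftl1 and Fth1 were at 3077 against 1249.9 CPM and 1027 against 433 CPM, and the oxidative stress list stood at 0.67 (12 of 14 genes higher). The autophagy list stood at 0.53, with only 10 of 18 genes higher. Hsph1 (1409 against 300.1 CPM; 2.22, 1.83 to 2.66), Hsp90aa1 (4219 against 1495 CPM; 1.49) and Hsp90ab1 (7537 against 4473 CPM; 0.75) were still higher. The chaperone list median was 0.29 (0.20 to 0.64), with 16 of 23 genes higher and 5 at least 2-fold higher (4 with the floor). Hspa1a was at 29.6 CPM against 0, or 1.71-fold over the floor, with a UMI in 5.77% of heated cells without thinning. Its log2 ratio of 3.38 became 1.62 without 45 °C 10 h cell 4. Both ratios rest on the 0.5 UMI added to a control at 0, so the value without that cell is no measured fold.

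Long noncoding RNAs and actin genes diverged at 10 h. The nuclear long noncoding RNA list stood higher (1.09; 10 of 12 genes, 9 above all unheated groups), with Gas5 at 785 against 369 CPM and Neat1, a paraspeckle scaffold, at 96.95 against 28.9 CPM. Actin cytoskeleton genes stood lower (-0.59; 18 of 19), with Actb at 6715 against 10612 CPM and Tmsb4x, an actin-binding peptide gene, at 1557 against 6216 CPM (-1.997, -2.11 to -1.88). Hk2, a hexokinase gene, was at 9.19 against 92.3 CPM (-3.30, -4.69 to -2.07), Cd96, a lymphocyte receptor gene, at 43.9 against 204.9 CPM and Tk1, thymidine kinase, at 51.03 against 207.8 CPM. ER genes stood lower (-0.55; 17 of 19), as did ribosome biogenesis genes (-0.42; 23 of 29), with Ncl, nucleolin, at 1368 against 1985 CPM. Ribosomal protein genes stood slightly higher (0.21; 65 of 76).

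With only 6 control cells at 10 h, several ratios leaned on 1 cell. Sqstm1 and Osgin1 stood at 5.35 and 3.06 without 37 °C 10 h cell 5, and Osgin1 stood at 3.54 against all unheated groups. Chd2, a chromatin remodeler gene, stood at 4.09, or 5.46 without cell 3. Tsc22d3, a glucocorticoid-induced gene, stood at 3.58, or 4.83 without cell 2, and Kctd20 at 2.53, or 3.415 without the same cell. Cx3cr1, a chemokine receptor gene, stood at -2.21, or -0.68 without cell 6. Against all unheated groups, Sqstm1, Chd2, Tsc22d3 and Kctd20 stood at 2.67, 1.405, 1.15 and 0.91, and for each of them the control at 10 h was the lowest unheated group. For Hk2, Tmsb4x, St6galnac4, Tk1, Cx3cr1 and Fam189b it was the highest, and against all unheated groups they stood at -2.87, -1.40, -2.615, -1.39, -1.285 and -1.61. Fam189b and St6galnac4 stood at -2.50 and -3.02, or -1.72 without cell 5 and -2.405 without cell 1.

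At 15 h after heating, few chaperone RNAs remained far above control. Hsp90aa1 was at 3769 against 1694.5 CPM (log2 1.15, 1.04 to 1.27) and Hsp90ab1 at 7645 against 5564 CPM (0.46). The chaperone list median was 0.13 (0.03 to 0.28), with 14 of 22 genes higher and 1 at least 2-fold higher, inside the unheated range, and it was -0.04 by the mean of per-cell CPM. Rn4.5s was at 2233 against 579.6 CPM, but its log2 ratio of 1.94 became 0.28 without 45 °C 15 h cell 4. Il4ra, an interleukin receptor gene, was higher (98.4 against 28.1 CPM), as were Dusp6, an ERK phosphatase gene (log2 1.17, 0.77 to 1.60), and Me1, malic enzyme (58.2 against 13.5 CPM). Fam46a and Ssfa2 stood at 2.23 and 1.98, or 1.63 without 45 °C 15 h cell 7 and 2.59 without 37 °C 15 h cell 3. Against all unheated groups, Fam46a, Ssfa2 and Me1 stood at 3.175, 1.246 and 3.423. For Fam46a and Me1 the control at 15 h was the highest unheated group.

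Mthfd2, Phgdh, Actg1 and Plk1 stood lower at 15 h. Mthfd2, a mitochondrial folate enzyme gene, was at 92.5 against 243 CPM (-1.39, -1.87 to -0.93) and Phgdh, of serine synthesis, at 300.5 against 529 CPM. The ATF4 list, which holds both, stood at -0.47 (11 of 12 genes lower), within its unheated range of -0.65 to 0.28. Actg1 was at 1417 against 2891 CPM (-1.03, -1.15 to -0.91), and the actin list stood at -0.36 (14 of 19 lower). Plk1, a mitotic kinase gene, was at 82.8 against 204.4 CPM (-1.30), the latter the highest unheated group, and stood at -0.92 against all unheated groups. The G2 and M phase list stood at -0.36 (31 of 35 lower) and the S phase list at 0.23, both inside their unheated ranges, but against the 45 °C arm before heating they stood at 0.08 and -0.35. ER genes stood lower (-0.39; 17 of 19), and so did nuclear respiratory chain genes (-0.27; 31 of 37), with Cox7b at 229.7 against 456 CPM. Heat shock factors stood at -1.199 over 3 measured genes, with Hsf1 at 25.4 against 62.9 CPM, but at 0.11 against the 45 °C arm before heating.

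Rbm3, a cold-induced RNA-binding protein gene and the only measured gene of its list, was lower from 5 h on. It was at 853 against 767 CPM at 1 h, then at 482 against 662.5 CPM at 5 h (-0.46), 415 against 746 CPM at 10 h (-0.85) and 379.6 against 714 CPM at 15 h (-0.91), below all 6 unheated groups at the later times. Chaperonin and prefoldin genes stood at 0.03, 0.02, -0.07 and -0.15 at 1, 5, 10 and 15 h, though at -0.028 at 1 h against all unheated groups, -0.025 against the 45 °C arm before heating and -0.033 with 1 cell left out, and at 5 h at -0.018 without Rn45s in the library size and -0.077 with 1 cell left out. Proteasome genes stood at -0.09, -0.13, -0.16 and -0.17, outside their unheated range (-0.02 to 0.08) at each time but inside it at 1 and 5 h relative to all genes, and at 0.085 at 1 h and 0.077 at 5 h with TMM library sizes. Splicing genes stood at -0.21, -0.19, 0.08 and -0.08, with Srsf3 at 208.1 against 517 CPM at 5 h. The 5 h median was 0.021 with TMM sizes, 0.010 against all unheated groups and 0.042 against the 45 °C arm before heating, and the 10 h median -0.07 by the mean of per-cell CPM, -0.033 against the 45 °C arm and -0.057 with 1 cell left out. Targets of p53 stood at 0.10, -0.14, 0.42 and 0.13 and apoptosis regulators at -0.34, -0.06, -0.11 and 0.17, and at 5 h both had the other sign with TMM sizes (0.076 and 0.15). Against the 45 °C arm before heating, p53 targets stood at -0.090 at 1 h and -0.278 at 15 h and apoptosis regulators at -0.196 at 15 h, and with 1 cell left out the lowest values were -0.088, -0.134 and -0.014. At 5 h apoptosis regulators stood at 0.015 with 5 CPM added and at up to 0.062 with 1 cell left out. The p53 median at 10 h lay inside its unheated range and between 0.075 (without 37 °C 10 h cell 1) and 1.202 (cell 2) with 1 cell left out, and the apoptosis median at 1 h lay outside its range (-0.30 to 0.12), but inside it relative to all genes. The interferon list had no measured gene at 1 h and stood at 0.36, 0.92 and 0.46 over 3, 2 and 1 genes at the later times, too few to read: at 5 h it stood at -0.09 against all unheated groups, -1.47 against the 45 °C arm before heating and -0.29 without 37 °C 5 h cell 4, at 10 h at 1.81 without 37 °C 10 h cell 2, and at 15 h at -0.17 against all unheated groups. Mitochondrially encoded genes were not analysed here.

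**Figure D4:**
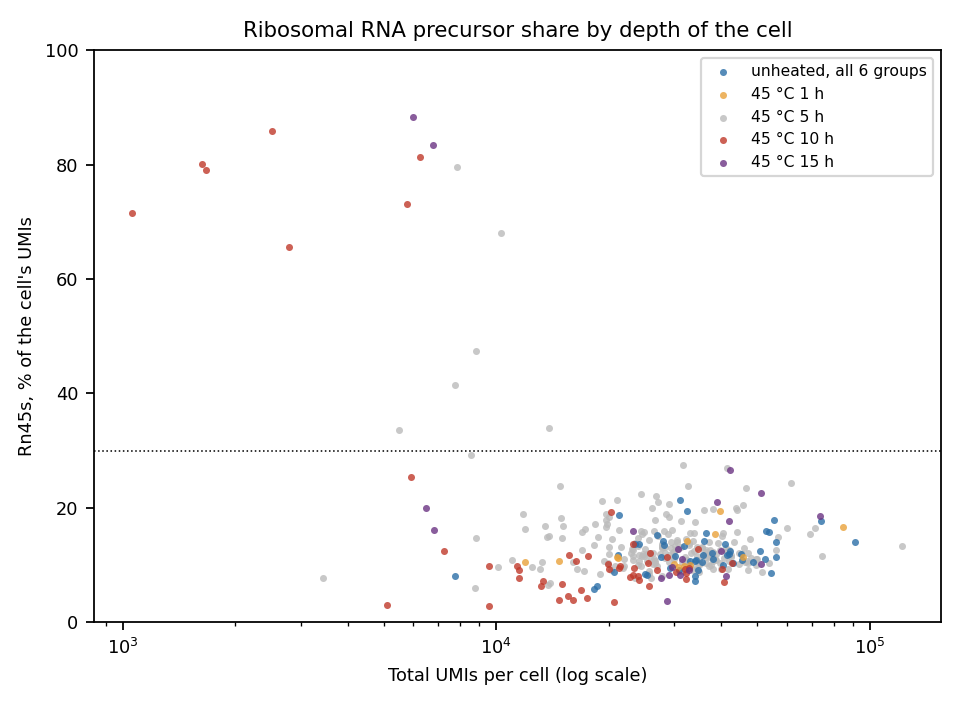
Share of each cell's UMIs in the ribosomal RNA precursor Rn45s against the total UMIs of the cell.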

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

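Each list below, with at least 5 genes measured, stood apart from random lists with a median above 0 at some time and with a median under 0 at another. That is what singled it out, and none of these differences was tested. Other lists also had medians on both sides of 0 without standing apart on both, such as immediate early genes (-0.45 at 1 h and 0.91 at 5 h). The ATF4 list went from -0.47 at 15 h to 0.28 at 5 h, a difference of 0.75, and its sign at 1 h and at 5 h depended on the control. The S phase list ranged from -0.36 at 5 h to 0.44 at 1 h, a difference of 0.80, but the arms differed by 0.47 before heating, and against the 45 °C arm before heating the 1 h median was -0.085. The nuclear long noncoding RNA list ranged from -0.66 at 1 h to 1.09 at 10 h, a difference of 1.75. Malat1 itself differed little at 10 h, with a median of 444 CPM per heated cell against 413 CPM per control cell. Actin cytoskeleton genes, such as Actb and Tmsb4x, ranged from -0.59 at 10 h to 0.13 at 1 h, a difference of 0.72, but the 1 h median was -0.081 against the 45 °C arm before heating.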

How the results depend on the processing

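The higher heat shock chaperone median at 5 h and 10 h kept its direction under every alternative, while those at 1 h and 15 h did not. At 1 h the median of 0.15 was -0.0065 against all unheated groups and 0.33 with TMM library sizes, and lay between 0.10 (without 45 °C 1 h cell 11) and 0.19 (cell 2) with 1 cell left out. At 5 h it was 1.09 with TMM sizes and lay between 0.80 (without 37 °C 5 h cell 3) and 0.99 (cell 4). At 10 h it was 0.14 by the mean of per-cell CPM and lay between 0.25 (without 45 °C 10 h cell 39) and 0.50 (37 °C 10 h cell 3). At 15 h it was -0.041 by the mean of per-cell CPM and 0.33 against the 45 °C arm before heating, and lay between 0.07 (without 45 °C 15 h cell 4) and 0.18 (37 °C 15 h cell 1). Chaperone genes at least 2-fold higher numbered 10 to 14 at 5 h, 4 to 6 at 10 h and 0 to 4 at 15 h.

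Other values that had stood apart, or had been named, changed sign. Against all unheated groups, the ATF4 list at 1 h stood at 0.235, glycolysis at 5 h at -0.10 and S phase at 15 h at -0.045. Against the 45 °C arm before heating, the values at 1 h were 0.055 for ATF4, -0.085 for S phase, 0.20 for G2 and M phase, -0.081 for actin and -0.019 for Casc4. With that control they were -0.24 for ATF4 and 0.054 for ribosome biogenesis at 5 h, and -0.35 for S phase, 0.080 for G2 and M phase and 0.11 for heat shock factors at 15 h. Ribosomal proteins at 15 h, at -0.0081, stood at 0.034 without Rn45s in the library size, at 0.018 without cells of over 30% Rn45s, and between -0.030 and 0.017 with 1 cell left out. The cause was not tested.

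Of 1044 comparisons of list medians, 100 changed sign, and 17 of these were of lists that had stood apart from random lists. Apart from those 17, 913 stayed within the counting interval of the first value, some with the other sign, and the rest lay outside it. For named genes, 796 of 880 stayed, 83 moved, of which 39 against the 45 °C arm before heating and 24 against all unheated groups, and 1 changed sign. Naming required a level outside the range of all unheated groups and the same direction with any single cell left out. This all but excluded beforehand a change of sign against these controls or with 1 cell left out. The count of sign changes is thus no test there. The 1 change, Casc4 at 1 h, came only from the 0.5 UMI added to each sum. Its 50.56 CPM exceeded the unheated maximum of 49.9 CPM. No paired analysis was possible because each group was 1 sample and the numbers in the labels only count cells. Library sizes from spike-ins, library sizes without mitochondrially encoded genes, and UMIs per spike-in UMI with its alternatives were not run, since those genes were not used here. The control groups at 5 h and 10 h, of 6 cells each, set the floor for genes at 0 and so limit what could be seen there.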

Other observations

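Leukocyte genes went different ways after heating. Ptprc was at 271 against 496 CPM at 5 h (log2 -0.88) and 291 against 482 CPM at 10 h (-0.73), and Coro1a was at 541 against 1119.6 CPM at 10 h (-1.05) and 634 against 1137 CPM at 15 h (-0.84), but at 919 against 939 CPM at 5 h. Laptm5, a lysosomal gene of leukocytes, was higher at 378 against 250.2 CPM at 5 h, 449.6 against 323 CPM at 10 h and 355 against 336 CPM at 15 h. Cd44, an adhesion receptor gene, was at 46.5 against 98.5 CPM at 5 h and 107.4 against 74.1 CPM at 15 h. Cd3g had log2 ratios of -0.625 at 10 h and -1.11 at 15 h, while Cd3e, at 217.1 CPM at 5 h, was near most unheated groups. At 5 h, Lrrc17, which encodes a secreted leucine-rich protein, varied most between cells of all protein-coding genes, with a Fano factor of 61.01 and unheated values of 3.08 to 27.1. Rn45s and Rn4.5s had Fano factors of 212.3 and 120.9, and Ccdc36 and Kif3a 11.2 and 10.7.

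For the polymerase III RNAs at 1 h, the tests on Rn45s and on the histone sum were chosen after the result was seen. A few cells did not account for the difference in the sum, which was mostly Rn4.5s, since 13 of 13 heated cells exceeded every unheated cell. Rpph1 and Rmrp, looked at alone without thinning, had a UMI in 12 and 13 of the 13 heated cells. In the 11 control cells they had a UMI in 1 and 0. More priming of ribosomal RNA was not seen, since Rn45s stood at 1.14-fold. The histone sum stood at a log2 ratio of -0.48 (-0.71 to -0.25), or between -0.69 and -0.07 with 1 cell left out. A gain of all RNAs without a poly(A) tail alike was thus seen in neither. Yet the histone sum was low at every time after heating, and such a fall could hide a gain. The test therefore cannot exclude this explanation. A gain shared with small nuclear and nucleolar RNAs stays open, since only 1 such gene was measured, Snord49b at 0.52. Rn4.5s resembles B1 repeats, and reads shared with those were not tested, so the cause stays open.

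For histone RNAs at 5 h, the S phase test was chosen after the result was seen. All 4 heated groups (615 to 765 CPM in the histone sum) lay below all 6 unheated groups (901 to 2210 CPM), with log2 ratios of -1.59 at 10 h and -1.11 at 15 h against other controls. The few control cells at 5 h still stay open as part of the reason, since against the other 5 unheated groups the ratio was -0.92, short of the limit of -1 set beforehand, and with TMM sizes the 5 h sum lay above the lowest unheated group (880.4 against 868 CPM). Reads shared between copies did not account for it, since the sum over all copies stood at -1.29. A lower share of S phase cells stays open: the S phase median exceeded the histone median by 1.21, but 3 of 31 S phase genes (Rrm2, Nasp and Ccne1) were as low as the histone median.

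For cells with over 30% of UMIs in Rn45s, the comparison with heating was chosen after the result was seen. Such cells made up 0 of 13 heated cells at 1 h, 2.69% (0.994% to 5.76%) at 5 h, 13.5% (5.59% to 25.8%) at 10 h and 9.52% (1.18% to 30.4%) at 15 h, and 0 of 51 unheated cells (upper limit 6.98%). The intervals at 10 h and in unheated cells overlap, which by the rule used left a link with heating open, but overlap is no test of a difference. The link stays open chiefly because each group was 1 sample. Some cells at 10 h were also shallow: the 10th percentile of UMIs outside Rn45s was 1208.5, against 18853.6 in unheated cells. No technical explanation was excluded for the cells with over 30% Rn45s.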
